A study of Mus musculus with 9 samples.

How the data were processed

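The data were single-cell gene expression profiles of hippocampi from 15-day-old C57BL/6J mice, in 9 libraries and 4 groups given by the labels. Per the labels' protocols, the tissue was dissociated with papain and cells were captured with the 10x Genomics 3′ version 2 chemistry, which tags each transcript with a UMI near its 3′ end, and sequenced on an Illumina NovaSeq instrument. The files the authors deposited hold UMI counts per gene and barcode, not normalised, for 27998 genes. The submitters' processing notes name Cell Ranger and the mouse genome build mm10; the version of Cell Ranger and its settings are not given in the sources used here. The counting decides what can be seen: genes that share sequence near their 3′ ends, as some class I, histone, chemokine and Saa family members do, can share or lose reads, and their values are less certain than those of other genes. Every library held both Xist and Y-linked transcripts. The labels do not say whether a library came from 1 animal or from a pool, so p-values measure the spread between libraries, which may be technical.

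The files held 56101 barcodes and 470028147 UMIs. The lowest UMI total of a barcode lay between 2508 and 4509 per library. By library, the total UMI counts were 42746987 in SS_1, 71465845 in SS_2, 34322768 in SL_1, 53878186 in SL_2, 49124840 in SL_3, 33811640 in LS_1, 60968329 in LS_2, 52738493 in LL_1 and 70971059 in LL_2. Barcodes per library ranged from 4012 to 8824. Counts of libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 84.61 to 132.15 over genes, and no library appeared to have been deposited more than once. At most 95 barcodes were shared between any pair of libraries.

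Barcodes with under 300 genes, under 500 UMIs or over 15% mitochondrial UMIs were removed (1152 in all; the UMI limit removed none). Doublets were scored with Scrublet in scanpy, and in each library the highest scores were removed at a rate of 0.8% per 1000 barcodes, 2951 in all (3.27 to 7.13% of a library). This left 51998 cells, 3813 to 8119 per library. Counts were scaled per cell and log-transformed, and 2000 variable genes were taken after leaving out the listed immune, stress, cell-cycle, sex-linked, mitochondrial and ribosomal genes. On 30 principal components a graph of 15 neighbours was clustered by the Leiden method at a resolution of 0.1. That resolution was chosen after the data were seen, because a resolution of 1.0 split several types by LPS state; the clusters at 1.0 are called fine clusters. Clusters were named from fixed markers by the mean log2 fold of the markers over the other clusters, with a pseudocount of 20 CPM, where at least 3 markers reached 50 CPM and the next class scored at least 1.5 lower. In 2 clusters the next class was a stage or type of the same lineage and the cluster was named all the same, oligodendrocyte precursors (scores of 3.55 for progenitors and 3.38 for committed precursors) and granule neurons (2.08, and 1.44 for excitatory neurons). These limits and this exception were also set after the data were seen, and 1398 cells in 6 clusters were left without a name. The groups, tests, alternatives, gene lists, cell type markers and the rule for naming genes were fixed before the data were examined.

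Counts were summed per library and class, leaving out a library with under 20 cells of the class, and tested with edgeR's quasi-likelihood F-test (TMM scaling, filterByExpr, robust dispersion) in a model with a mean for each of the 4 groups, which leaves 5 residual degrees of freedom and shares 1 estimate of the spread. Contrasts were SL against SS, LL against LS, LS against SS, LL against SL, the interaction, and each injection averaged over the other. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 per class and contrast. There were 31 gene lists and 22 marker lists, 53 in all, tested with limma's camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the lists tested in a class and contrast. Endothelial cells, microglia, astrocytes and oligodendrocytes were the 4 main classes. The second-hit score used genes called in a model of the second injection alone, and its difference was tested by exact permutation of the first-injection labels within each second injection (60 arrangements). Shares of cells were tested by exact permutation over 126 splits of the libraries, 2-sided, adjusted over 17 classes.

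Genes were named in the text by a fixed rule. For each contrast and main class it took the 3 largest rises and 3 largest falls among called genes whose libraries did not overlap between the groups, with a mean of at least 50 CPM in 1 of the groups and a class mean of at least 10% of that in the class with the highest mean. For the interaction the limit on overlap was not applied. Predicted, ribosomal, mitochondrial, haemoglobin and sex-linked genes were skipped among these rises and falls. To these it added up to 4 called members of each list by smallest adjusted p and, for lists with none, the 2 members with the highest CPM as values. In the other classes it took 2 rises and 2 falls for the averaged second injection. Genes at 0 or near 0 in the comparison group are given as CPM without a fold. RNA released from broken cells adds UMIs to every droplet, so genes far below their level in another class were also left out as an alternative.

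The count test was tested on simulated data with 200 changed genes for SL against SS. At a fold of 2, edgeR recovered 41 of 100 genes in endothelial cells, 30 in microglia, 42 in astrocytes and 44 in oligodendrocytes, and at a fold of 4 it recovered 80, 84, 80 and 90. False calls made up 6.34, 7.2, 5.15 and 7.69% of its calls, over 12315, 9691, 13580 and 10708 genes. With DESeq2 they made up 12, 8.7, 12.9 and 9.8%. In the simulated LL against LS, where nothing changed, edgeR called 1, 1, 0 and 0 genes, and camera called the changed list and 0 of 30 unchanged lists in each class. Simulated genes were drawn independently of each other, so this does not test false list calls among correlated genes. The score test on simulated microglia gave an exact p under 0.05 in 1 of 20 simulations with an equal response (median 99.8%) and in 4 of 20 with a response of 50% in LL (median 58.1%). The score can therefore give a percentage above the true one when the response in LL is smaller.

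Alternatives were DESeq2's Wald test and its size factors, no filter on low counts, fitting only the compared groups, a block for the replicate number, doublets kept, a stricter cell filter (1000 genes, 2000 UMIs, 10% mitochondrial), classes assigned per cell by marker score, leaving out genes below 10% of their level in the class with the highest mean, the 100 genes with the smallest p for the score, and each library left out in turn. Where that left 1 library in a group, its spread was assumed to be that of the other groups. An alternative with a factor for the library with the highest median UMI count per barcode in each group, for oligodendrocytes, was added after the data were seen. Gene coordinates are from GENCODE vM21 on GRCm38, the assembly that mm10 names, matched by gene identifier (27645 of 27998, 98.7%). Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.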

Results

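Single-cell RNA libraries were made from the hippocampi of C57BL/6J mice on postnatal day 15, to ask whether systemic inflammation soon after birth alters how hippocampal cells respond to a later inflammatory challenge. Mice received 5 mg/kg of lipopolysaccharide (LPS) or saline under the skin on day 3, and LPS at 5 mg/kg or saline into the abdominal cavity on day 14. LPS is an outer-membrane component of Gram-negative bacteria that activates Toll-like receptor 4. Tissue was taken 24 h after the injection on day 14. The first letter of a group name gives the first injection and the second letter the second one, with S for saline and L for LPS. There were 2 SS, 3 SL, 2 LS and 2 LL libraries. They held 33811640 to 71465845 unique molecular identifiers (UMIs), with a median of 5115 to 9215 UMIs and 2105 to 2976 genes per barcode. After filtering, 51998 cells remained. Clusters were called by the cell type whose markers, fixed before the data were examined, they expressed, and each name below stands for cells like that type. The classes with most cells were astrocytes (14653), immature neurons (9415), oligodendrocyte precursors (5360), endothelial cells (4984), microglia (2855) and oligodendrocytes (2184). The microglial cluster was led by the chemokine genes Ccl4, Ccl3 and Ccl12, ahead of the complement genes C1qc, C1qb and C1qa. Expression is given as CPM, a class's summed UMIs scaled to a common library total with edgeR's TMM factors, as mean ± SD over the libraries of a group. Changes are log2 fold changes ± standard error from edgeR's quasi-likelihood test, with p-values adjusted by the Benjamini-Hochberg method.

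LPS on day 14 after saline on day 3 (SL against SS) changed endothelial cells through genes of antigen presentation, interferon signalling, NF-kB signalling and the acute phase. All 16 measured genes of MHC class I antigen presentation rose, as did 20 of 21 inflammatory cytokines and NF-kB targets, and of 29 interferon-stimulated genes 27 rose and 1 fell. H2-K1 (chromosome 17, 33996017 to 34000347, minus strand, GRCm38), which encodes a class I molecule that presents peptides to T cells, went from 96.3 ± 21 CPM in SS to 989 ± 125 CPM in SL (3.36 ± 0.20, adjusted p = 3.6e-05). Lcn2 (chromosome 2, 32384633 to 32388252, minus strand), encoding the iron-siderophore-binding acute-phase protein lipocalin 2, went from 19.6 ± 13.6 to 13091 ± 3562 CPM (9.44 ± 0.64, adjusted p = 0.00018). The chemokine gene Cxcl12 (chromosome 6, 117168535 to 117181367, plus strand) fell by 3.52 ± 0.37 on the log2 scale, from 928 ± 15 to 80.4 ± 43.2 CPM (adjusted p = 0.00085). In all, edgeR called 1598 of 12524 genes, 914 higher and 684 lower.

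Among the endothelial interferon-stimulated genes, the membrane restriction factor gene Ifitm3 rose by 3.77 ± 0.27, Oasl2 by 3.17 ± 0.23 and Xaf1 by 1.70 ± 0.14. Of the NF-kB group, Nfkbia (chromosome 12, 55489410 to 55492647, minus strand), the inhibitor that NF-kB itself induces, rose by 1.90 ± 0.23, the NF-kB subunit genes Relb and Nfkb2 by 1.62 ± 0.21 and 1.87 ± 0.25, and Ptgs2, which encodes cyclooxygenase 2, by 5.13 ± 1.02 (adjusted p = 0.019). Antigen processing rose at the immunoproteasome gene Psmb8 (2.87 ± 0.21) and at Tapbp (2.09 ± 0.15). Of 12 adhesion molecules, 7 rose and 1 fell. The leukocyte adhesion receptor gene Vcam1 (chromosome 3, 116109949 to 116129688, minus strand) rose by 4.01 ± 0.30, the venular chemokine receptor gene Ackr1 (chromosome 1, 173331886 to 173333750, minus strand) by 6.46 ± 0.74, and Vwf by 1.48 ± 0.22. Acute-phase and STAT3 response genes rose in 13 of 16 members and complement genes in 8 of 13. The complement protease gene C1ra went from 0.475 ± 0.0406 to 93.2 ± 21.5 CPM (adjusted p = 5.1e-05), and Serpina3n from 0.783 ± 0.318 to 370.4 ± 88.3 CPM (adjusted p = 8.1e-05). Of 7 MHC class II genes, 5 rose. Unfolded protein response genes rose in 8 of 14 members, among them the chaperone gene Hspa5 (1.10 ± 0.18) and the transcription factor gene Xbp1 (1.75 ± 0.18).

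Some endothelial genes of Wnt signalling, the cell cycle, angiogenesis and the blood-brain barrier fell, although most members of these lists were not called. Of 11 Wnt/beta-catenin targets, 5 fell, including Tcf7 by 1.39 ± 0.16 and Sox17 by 0.87 ± 0.18. Cell-cycle genes fell in 11 of 27 members, including the mitotic genes Birc5 (chromosome 11, 117849251 to 117855743, plus strand) by 2.39 ± 0.47 and Ube2c by 2.35 ± 0.39. Of 17 angiogenesis and tip-cell genes, 5 fell and 2 rose; Apln, which encodes a tip-cell ligand, fell by 1.99 ± 0.40. Of 22 blood-brain barrier junction and transporter genes, 4 fell and 2 rose. Those that fell included Mfsd2a (chromosome 4, 122946850 to 122961188, minus strand), the lipid transporter gene that limits transcytosis, by 1.63 ± 0.37 and the transferrin receptor gene Tfrc by 1.84 ± 0.23, while the glucose transporter gene Slc2a1 rose by 0.93 ± 0.17. The counts adjusted over the list alone were 16 of 16 for MHC class I, 28 higher and 1 lower for interferon-stimulated genes, 20 for NF-kB targets, 9 for complement, 15 for the acute phase, 9 higher and 2 lower for adhesion molecules, 7 lower for Wnt targets, 14 lower with 1 higher for the cell cycle, 8 lower with 3 higher for angiogenesis, 4 lower with 2 higher for the barrier list, and 6 and 9 higher for class II and the unfolded protein response. The camera list test called all of these lists; with an estimated correlation the adjusted p was 0.0478 for both MHC class I and complement, and the call was lost for interferon-stimulated genes (adjusted p = 0.0655), NF-kB targets (0.0726), the acute phase (0.0726), adhesion molecules (0.0655), Wnt targets and the cell cycle (0.276 each), the unfolded protein response (0.0955), class II (0.23), and the barrier and angiogenesis lists (0.498 each). Of 14 homeostatic microglia genes measured in endothelial cells, 5 fell, and 11 when adjusted over the list alone. Most SS endothelial cells lay in fine cluster 6 (951 cells) and most SL cells in fine clusters 19 (834) and 14 (348). Without SS_1 the call count was 1049, and without SS_2 it was 664.

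In microglia the same comparison called genes of the resting state lower, and interferon-stimulated genes and some chemokine and acute-phase genes higher. Of 18 homeostatic microglia genes, 17 fell and none rose. P2ry12 (chromosome 3, 59216272 to 59262871, minus strand), the ADP receptor gene by which resting microglia sense injury, fell by 4.73 ± 0.50, from 1848 ± 220.2 to 68.8 ± 36.2 CPM (adjusted p = 0.00066). The fructose transporter gene Slc2a5 (chromosome 4, 150119283 to 150144169, plus strand) fell by 6.19 ± 0.40, from 115 ± 5.9 to 1.24 ± 1.34 CPM. Saa3 (chromosome 7, 46711998 to 46715700, minus strand), encoding a serum amyloid A acute-phase protein, went from 0.478 ± 0.676 to 38480.5 ± 10688 CPM (adjusted p = 5.5e-07), and the scavenger receptor gene Marco from 0 to 1502 ± 633 CPM (adjusted p = 0.00025). Cd52 (chromosome 4, 134082448 to 134095082, minus strand), encoding a leukocyte surface glycoprotein, rose by 3.20 ± 0.20 (adjusted p = 9.8e-08). The test called 2319 of 10024 genes, 1282 higher and 1037 lower.

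Microglial interferon-stimulated genes rose in 17 of 25 members, with Irf7 at 3.63 ± 0.37, Isg15 at 2.39 ± 0.25 and Bst2 at 2.03 ± 0.19. Of 15 chemokines, 5 rose and 2 fell; Ccl12 rose by 3.47 ± 0.28, Ccl5 by 4.99 ± 0.58 and Cxcl16 by 2.13 ± 0.20. NF-kB targets and cytokines rose in 9 of 20 members, among them the Toll-like receptor gene Tlr2 (1.62 ± 0.20) and Il1b, encoding interleukin 1 beta (3.37 ± 0.65, adjusted p = 0.012). The acute-phase list held 7 genes that rose and 2 that fell of 16. Unfolded protein response genes rose in 8 of 13 members, including Sdf2l1 (2.09 ± 0.19) and Manf (1.75 ± 0.17), and glycolysis genes in 9 of 15, including Gapdh (1.65 ± 0.20) and Ldha (1.58 ± 0.19). The iron-storage gene Fth1 rose by 2.35 ± 0.15. Further homeostatic genes that fell were Gpr34 by 4.47 ± 0.37, Fcrls (chromosome 3, 87250758 to 87263738, minus strand) by 2.65 ± 0.22, Tmem119 by 1.90 ± 0.26 and Csf1r, the receptor gene for the microglial survival factor CSF1, by 1.20 ± 0.18. The lysosomal protease gene Ctsd fell by 2.46 ± 0.21. Immediate-early genes, which tissue dissociation can induce, fell in 10 of 19 members, including Atf3 by 1.57 ± 0.16 and Jund by 1.71 ± 0.19.

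When adjusted over the list alone, 18 of 18 homeostatic microglia genes were lower, 18 interferon-stimulated genes were higher and 1 lower, and 8 chemokines were higher and 2 lower. The corresponding counts were 12 higher and 1 lower for NF-kB targets, 8 higher and 2 lower for the acute phase, 8 higher and 1 lower for the unfolded protein response, 9 higher for glycolysis and 11 lower for immediate-early genes. The camera test called these 8 lists, and none of its 11 calls in this comparison held with an estimated correlation: the adjusted p was 0.17 for homeostatic, interferon-stimulated and acute-phase genes, 0.174 for immediate-early genes, 0.332 for chemokines, 0.343 for the unfolded protein response, 0.348 for glycolysis and 0.589 for NF-kB targets. Most SS microglia lay in fine cluster 20 (352 cells) and SL microglia in fine clusters 21 (767) and 16 (313). Without SS_1 the test called 1440 genes, and without SS_2 it called 1129.

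Astrocytes of SL libraries carried higher levels of reactive-astrocyte, interferon and antigen presentation genes. All 11 measured A1 astrocyte genes rose, with 12 of 13 pan-reactive genes and 28 of 30 interferon-stimulated genes. Gfap (chromosome 11, 102887336 to 102900912, minus strand), the intermediate filament gene that marks reactive astrocytes, went from 1729 ± 82.1 to 4951 ± 1089.9 CPM (1.52 ± 0.25, adjusted p = 0.01). Lcn2 went from 0.278 ± 0.0197 to 5046 ± 3885 CPM (adjusted p = 0.0041) and the metalloreductase gene Steap4 from 0.442 ± 0.476 to 503 ± 369 CPM (adjusted p = 0.0059). Serpina3n rose by 5.23 ± 0.60, Aspg by 4.41 ± 0.39, the complement gene C4b by 2.90 ± 0.21, and the A1 genes Srgn and Ggta1 by 3.94 ± 0.29 and 3.39 ± 0.27. Of 16 MHC class I genes, 14 rose, led in significance by Psmb9 and Psmb8 (4.67 ± 0.44), and of 7 class II genes 6 rose, including H2-Ab1 (4.37 ± 0.46). Of the interferon-stimulated genes, Oasl2 rose by 4.55 ± 0.38. NF-kB targets rose in 12 of 21 members, with Nfkbia at 2.85 ± 0.46 and Relb at 2.81 ± 0.45. Acute-phase genes rose in 9 of 17 members, and A2 astrocyte genes in 5 of 12, including the pentraxin gene Ptx3 (5.25 ± 1.14, adjusted p = 0.038). Cholesterol synthesis genes fell in 4 of 20 members, Dhcr7 by 1.08 ± 0.18, Mvk by 1.05 ± 0.20, Mvd by 0.98 ± 0.21 and Nsdhl by 0.87 ± 0.17. The matrix genes Myoc and Hapln1 fell by 2.58 ± 0.34 and 1.54 ± 0.37, and the circadian transcription factor gene Dbp by 1.42 ± 0.30.

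In astrocytes edgeR called 1137 of 13751 genes, 786 higher and 351 lower. In tests adjusted over the list alone, 11 A1, 13 pan-reactive, 29 interferon-stimulated, 15 MHC class I, 6 class II, 18 NF-kB, 12 acute-phase and 8 A2 genes were higher, and 4 cholesterol synthesis genes were lower. The camera test called 20 lists, none with an estimated correlation: the adjusted p was 0.0768 for A1, interferon-stimulated and class II genes, 0.0897 for class I and the acute phase, 0.103 for pan-reactive genes, 0.141 for NF-kB targets, 0.519 for A2 genes and 0.715 for cholesterol synthesis. Of the SL astrocytes, 1949 lay in fine cluster 5, which held 1 SS, 0 LS and 10 LL cells. The count rested on single libraries: it was 235 without SS_1, 23 without SS_2, 2398 without SL_2, 403 without SL_3, 566 without LL_1 and 558 without LL_2, and 376 when SS and SL libraries were fitted alone.

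Oligodendrocytes had 49 genes higher and 5 lower of 10837 in SL, among them 13 of 22 interferon-stimulated genes, all of which rose. Usp18, whose product removes the ubiquitin-like ISG15, went from 0 to 37 ± 7.26 CPM (adjusted p = 4.7e-05). Ifitm3 rose by 3.20 ± 0.23 and the class I light chain gene B2m by 2.16 ± 0.31, although their mean level in oligodendrocytes was 0.01 and 0.02 of that in the class with the highest mean. The aminotransferase gene Bcat1 (adjusted p = 0.013) and the RNA polymerase III subunit gene Polr3e (1.81 ± 0.31, adjusted p = 0.033) also rose. Saa3 was at 308 ± 158 CPM in SL oligodendrocytes, and, with CPM of plain class totals without TMM factors, 0.815 to 1.48 times its mean level in 3 classes of neurons of the same libraries. Adjusted over the list alone, 21 of 22 interferon-stimulated genes were higher, and the list kept its call with an estimated correlation (adjusted p = 0.00108). The list test was not repeated without genes far below their level in another class, so RNA from other cells stays open for it. The count of called genes was 21 once genes far below their level in another class were left out, and higher with a block for the replicate number. It was 20 without SS_1, 14 without SS_2, 35 without SL_1, 86 without SL_2, 33 without SL_3, and 35 without LL_1 or LL_2.

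**Figure D1:**
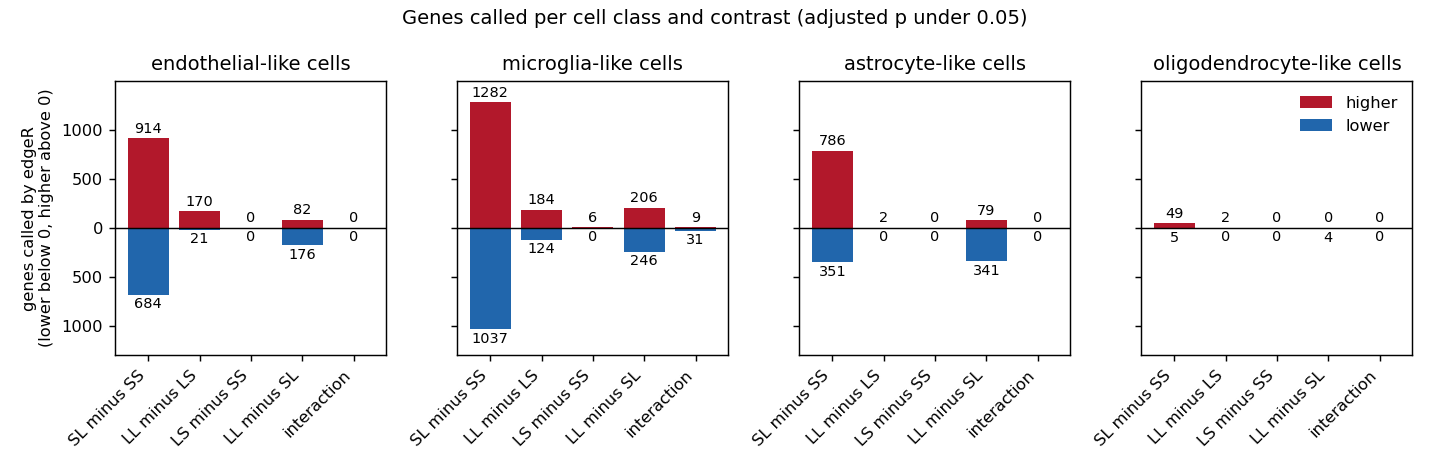
Number of genes called by edgeR at an adjusted p under 0.05 (vertical axis, genes; bars above 0 are genes called higher and bars below 0 genes called lower) for the 5 comparisons on the horizontal axis in each of 4 cell classes. SL against SS gave the most calls in each class, from 54 in oligodendrocytes to 2319 in microglia, and LS against SS gave 6 in microglia and 0 in the other 3 classes.

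LPS on day 14 was also tested in mice that had received LPS on day 3 (LL against LS). In endothelial cells the interferon-stimulated genes and MHC class I genes rose again, with 28 of 29 and 14 of 16 members called. H2-K1 went from 90.4 ± 12.6 CPM in LS to 935 ± 57.4 CPM in LL (3.38 ± 0.20, adjusted p = 0.0001). Oasl2 rose by 3.43 ± 0.25, Bst2 by 2.83 ± 0.21, Rtp4 by 2.28 ± 0.19, Xaf1 by 1.84 ± 0.15, the class I genes H2-D1 and B2m by 2.26 ± 0.16 and 2.68 ± 0.23, and Psmb8 by 2.56 ± 0.22. NF-kB targets were called in 2 of 21 members, the interleukin 1 receptor gene Il1r1 (1.83 ± 0.26, adjusted p = 0.0061) and Il1b, whose endothelial mean was 0.02 of that in the class with the highest mean. Acute-phase genes rose in 3 of 16 members, with Lcn2 going from 9.68 ± 0.646 to 1521 ± 427 CPM (adjusted p = 0.0019), and complement genes in 6 of 13, including Cfb, from 0.629 ± 0.305 to 55.1 ± 29.9 CPM. Adhesion molecules rose in 3 of 12 members, Vcam1 by 3.01 ± 0.30, Ackr1 by 5.52 ± 0.73 (adjusted p = 0.014) and Vwf by 1.40 ± 0.24. Fewer genes fell, 21 against 170 that rose, of 12524. They included the matrix gene Ltbp4 by 1.60 ± 0.24, the lipase gene Mgll by 1.48 ± 0.23, Tfrc by 1.36 ± 0.26 and the Wnt target Nkd1 by 1.02 ± 0.22. The erythroid transcripts Hbb-bs and Hba-a2 also fell, by 2.30 ± 0.35 and 2.24 ± 0.38.

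Tests adjusted over the list alone put 28 interferon-stimulated, 16 MHC class I, 8 complement, 7 NF-kB and 7 acute-phase genes higher in LL endothelial cells, with 5 adhesion molecules higher and 2 lower. With an estimated correlation the camera call held for interferon-stimulated genes (adjusted p = 0.0143), MHC class I (0.0135) and complement (0.0125), and was lost for NF-kB targets (adjusted p = 0.258), the acute phase (0.169) and adhesion molecules (0.0936). LS endothelial cells lay mainly in fine cluster 6 (708 cells) and LL cells in fine cluster 14 (602). The count was 92 without LS_1, 84 without LS_2 and 62 without LL_1.

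LL microglia differed from LS microglia in 308 of 10024 genes, 184 higher and 124 lower. Interferon-stimulated genes rose in 12 of 25 members, with Ifitm3 at 3.03 ± 0.32, Irf7 at 3.27 ± 0.40 and Bst2 at 1.60 ± 0.20, and the cytosolic DNA sensor gene Ifi204 rose by 3.74 ± 0.39. Of 15 chemokines, 3 rose and 1 fell. Ccl12 rose by 2.75 ± 0.28, and Cxcl13, which encodes a B-cell attractant, went from 4.13 ± 2.54 to 371 ± 135 CPM (adjusted p = 0.035). Saa3 went from 0 to 1120.4 ± 107 CPM (adjusted p = 6.6e-05). Homeostatic genes fell in 3 of 18 members, Sparc by 1.61 ± 0.26, Gpr34 by 2.01 ± 0.39 and Slc2a5 by 1.62 ± 0.38. The iron exporter gene Slc40a1 fell by 2.82 ± 0.30 and the prostaglandin-degrading enzyme gene Hpgd by 2.04 ± 0.45. NF-kB targets rose in 2 of 20 members, Tlr2 by 1.32 ± 0.21 and Tnfaip3, a deubiquitinase gene that restrains NF-kB, by 1.33 ± 0.29. Unfolded protein response genes rose in 4 of 13 members and glycolysis genes in 4 of 15, with Sdf2l1 at 1.72 ± 0.20 and Gapdh at 1.31 ± 0.21. Adjusted over the list alone, 18 interferon-stimulated genes, 7 NF-kB, 7 glycolysis and 6 chemokine genes were higher, 1 chemokine was lower, 14 homeostatic genes were lower, and 7 unfolded protein response genes were higher and 1 lower. None of the 16 camera calls held with an estimated correlation, with an adjusted p of 0.107 for interferon-stimulated genes, 0.283 for chemokines, 0.51 for homeostatic genes, 0.579 for glycolysis, and 0.596 for both NF-kB targets and the unfolded protein response. LS microglia lay mainly in fine cluster 20 (441 cells) and LL microglia in fine cluster 16 (583). The count was 109 without LS_1, 58 without LS_2, 68 without LL_1 and 94 without LL_2, and 196 with doublets kept.

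In astrocytes, LL against LS gave 2 calls of 13751, Spon1 and Saa3. Spon1 (chromosome 7, 113765998 to 114043370, plus strand), which encodes an extracellular matrix protein, was at 18.8 ± 1.82 CPM in LS and rose by 1.68 ± 0.14 (adjusted p = 0.0038), and Saa3 went from 0.0536 ± 0.0758 to 16.6 ± 1.35 CPM, under 0.01 of its level in the class with the highest mean. Adjusted over the list alone, 15 of 30 interferon-stimulated and 7 of 11 A1 genes were higher, although camera's calls of these lists had an adjusted p of 0.316 with an estimated correlation. Oligodendrocytes also gave 2 calls, among them Irf7 (4.71 ± 0.53, adjusted p = 0.016). Neither gene was called once genes far below their level in another class were left out. The 22 interferon-stimulated genes of oligodendrocytes had 13 members higher when adjusted over the list alone and kept the camera call with an estimated correlation (adjusted p = 0.003). That list test was not repeated without genes far below their level in another class, so RNA from other cells stays open for it. Both counts of 2 calls were small and moved with single libraries, in astrocytes to 4 without SL_2, 1 without LS_1 and 0 without LS_2 or LL_2, and in oligodendrocytes to 1 without SL_2 or SL_3 and 0 without either LS or LL library. DESeq2 called 40 genes in astrocytes and 5 in oligodendrocytes.

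Comparing LS with SS asked what remained on day 15 of LPS given on day 3, in mice with saline on day 14. Microglia were the class of the 4 with calls, 6 genes of 10024, all higher in LS. Cd52 was at 289 ± 10.5 CPM in SS and 918 ± 140.1 CPM in LS (1.67 ± 0.20, adjusted p = 0.0028). No list kept a camera call with an estimated correlation; that of the chemokines, lower in LS with 3 of 15 members when adjusted over the list alone, had an adjusted p of 0.0939. The microglial count was 0 without SS_1 or SS_2, 3 without LS_2, 16 without SL_1, 13 without SL_2 and 22 by DESeq2. In endothelial cells, astrocytes and oligodendrocytes edgeR called 0 genes and DESeq2 called 0. At an unadjusted p under 0.05 there were 112 genes in endothelial cells, 69 in astrocytes and 82 in oligodendrocytes, against 539 in microglia. By chance alone a share of 0.05 of the tested genes would pass, which is near the microglial count and far above the other counts. Same-numbered SS and LS libraries deviated together, with correlations of 0.632 in astrocytes, 0.554 in endothelial cells, 0.274 in microglia and 0.554 in oligodendrocytes. The test took libraries as unpaired, so its spread may be too wide for this comparison. The 0 calls therefore do not show that nothing remained of the first injection.

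Among mice given LPS on day 14, those with LPS on day 3 were compared with those without it (LL against SL). In LL endothelial cells, 9 of 21 NF-kB targets and 8 of 16 acute-phase genes were called lower. Nfkbia was at 4282 ± 845 CPM in SL and 1780.0 ± 159.8 CPM in LL, against 1151 ± 295 CPM in SS, and fell by 1.27 ± 0.22 on the log2 scale (adjusted p = 0.024). Tnip1, encoding a partner of the NF-kB inhibitor A20, fell by 3.12 ± 0.44, Bcl3 by 2.59 ± 0.37, Irak3 by 2.92 ± 0.37, Serpina3n by 3.45 ± 0.39 and Lcn2 by 3.11 ± 0.46. The adhesion gene Vcam1 also fell (adjusted p = 0.023), Cxcl16 fell by 1.80 ± 0.22, and the unfolded protein response genes Xbp1 and Manf by 1.31 ± 0.17 and 1.07 ± 0.14. None of the 29 interferon-stimulated or 16 MHC class I genes was called. H2-K1 was at 989 ± 125 CPM in SL and 935 ± 57.4 in LL, and Oasl2 at 99.5 ± 2.88 and 120.2 ± 36. Genes higher in LL included Cxcl12 (2.40 ± 0.36, adjusted p = 0.021), Dbp (2.05 ± 0.24), the iron exporter gene Slc40a1 (1.99 ± 0.37), the caveolar coat gene Cav1 (1.57 ± 0.23), the Wnt target Tcf7 (0.91 ± 0.16) and the vascular endothelial growth factor receptor genes Kdr (0.91 ± 0.20) and Nrp1 (0.86 ± 0.18). In all, 82 genes were higher and 176 lower of 12524. For LL against SL, adjusted over the list alone, 18 NF-kB targets and 11 acute-phase genes were lower, 7 unfolded protein response genes were lower, 7 Wnt targets were higher, and among interferon-stimulated genes 1 was higher and 3 were lower. None of the 22 camera calls held with an estimated correlation (adjusted p = 0.11 for NF-kB targets, the acute phase and the unfolded protein response, 0.326 for Wnt targets, 0.689 for interferon-stimulated genes). SL cells lay mainly in fine cluster 19 (834 cells) and LL cells in fine cluster 14 (602). The count was 93 without SL_1, 534 without SL_2, 85 without SL_3, 11 without LL_1 and 0 without LL_2.

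In microglia, LL against SL called some acute-phase and chemokine genes lower and some homeostatic genes higher. Acute-phase genes fell in 4 of 16 members and rose in 1, with Saa3 at 38480.5 ± 10688 CPM in SL and 1120.4 ± 107 in LL. Chemokines fell in 6 of 15, of which Ccl5 fell by 4.40 ± 0.55, Ccl3 by 1.27 ± 0.25 and Ccl12 by 1.17 ± 0.24. Fth1 fell by 1.37 ± 0.14, Cd52 by 0.93 ± 0.18 and Isg15 by 0.80 ± 0.20, and Marco was at 1502 ± 633 CPM in SL and 20.9 ± 8.32 in LL. Interferon-stimulated genes fell in 3 of 25 members. Homeostatic genes rose in 3 of 18, Fcrls by 1.37 ± 0.21 (adjusted p = 0.0034), Slc2a5 by 2.95 ± 0.47 and the transforming growth factor receptor gene Tgfbr1 by 0.98 ± 0.24. The phospholipase gene Pld4 rose by 1.75 ± 0.32, Gas6, a ligand of phagocytic receptors, by 2.02 ± 0.30, the apolipoprotein gene Apoc1 by 2.16 ± 0.36, and the lysosomal genes Cd68 and Ctsd by 1.01 ± 0.21 and 1.02 ± 0.21. Of 10024 genes, 206 were higher and 246 lower. Adjusted over the list alone, 16 of 18 homeostatic genes were higher, 6 chemokines were lower, 2 acute-phase genes were higher and 6 lower, and 1 interferon-stimulated gene was higher and 4 lower, a list that camera did not call. None of its 16 calls held with an estimated correlation (adjusted p = 0.53 for homeostatic genes, 0.198 for chemokines, 0.233 for the acute phase). SL microglia lay mainly in fine cluster 21 (767 cells) and LL microglia in fine cluster 16 (583). The count was 199 without SL_1, 89 without LL_1 and 64 without LL_2.

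LL astrocytes had lower reactive-astrocyte genes than SL astrocytes, with 9 of 13 pan-reactive, 9 of 11 A1, 9 of 30 interferon-stimulated, 8 of 21 NF-kB and 7 of 16 MHC class I genes called lower. Lcn2 was at 5046 ± 3885 CPM in SL and 36.1 ± 11.7 in LL (adjusted p = 0.028), and Gfap fell by 1.21 ± 0.25 (adjusted p = 0.043). Aspg fell by 3.24 ± 0.36, Srgn by 2.27 ± 0.25, Psmb8 by 2.61 ± 0.39, Nfkbia by 2.92 ± 0.46 and Fth1 by 1.85 ± 0.29. Genes higher in LL included Dbp (1.56 ± 0.31), the thyroid hormone transporter gene Slco1c1 (1.46 ± 0.28) and the glutamine transporter gene Slc38a3 (1.05 ± 0.20). Of 13751 genes, 79 were higher and 341 lower. With p adjusted over the list alone, 13 pan-reactive, 11 A1, 26 interferon-stimulated, 19 NF-kB and 15 class I genes were lower. None of the 20 camera calls held with an estimated correlation (adjusted p = 0.159 for pan-reactive, 0.101 for A1, 0.167 for NF-kB, and 0.179 for interferon-stimulated and class I genes). The count was 144 without SS_1, 153 without SS_2, 260 without SL_1, 1663 without SL_2, 4 without SL_3, 209 without LS_1, 215 without LS_2 and 0 without either LL library. Oligodendrocytes gave 4 calls, all lower in LL: Lcn2, Usp18, which fell by 2.77 ± 0.30, Nfkbia by 1.46 ± 0.21 and Ifitm3 by 1.40 ± 0.20. Lcn2, Nfkbia and Ifitm3 stood at about 0.01 of their level in the class with the highest mean. Leaving out genes far below their level in another class lowered the count of 4 calls, while a block for the replicate number raised this count. That count was 15 without SL_2 and 0 without SL_3, LL_1 or LL_2. The interferon-stimulated list was lower in 17 of 22 members when adjusted over the list alone, and its call held with an estimated correlation (adjusted p = 0.00381). Here too the list test was not repeated without genes far below their level in another class, so RNA from other cells stays open for it.

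**Figure D2:**
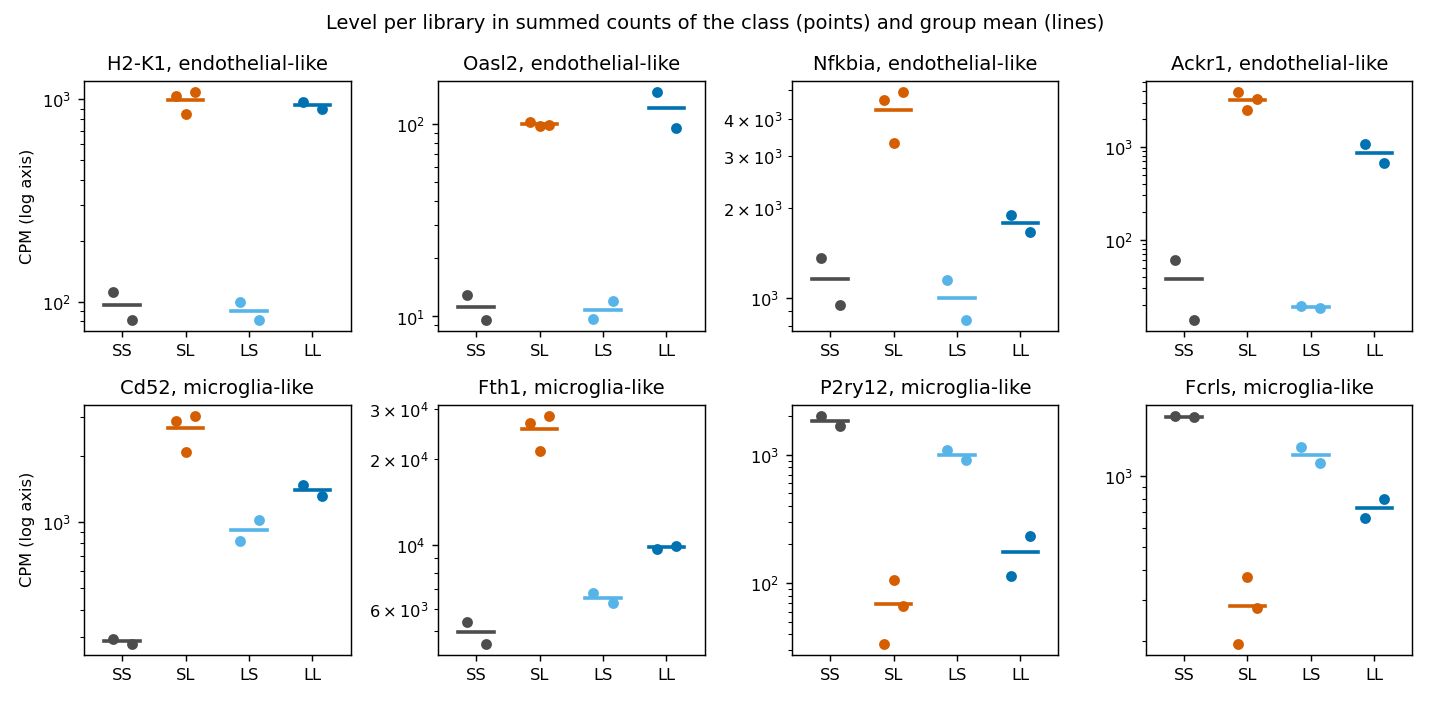
CPM per library (log axis) of 4 genes in endothelial cells (H2-K1, Oasl2, Nfkbia, Ackr1) and 4 in microglia (Cd52, Fth1, P2ry12, Fcrls), with a point per library and a line at the mean of each of the groups SS, SL, LS and LL. Endothelial H2-K1 averages 989 CPM in SL and 935 in LL, while endothelial Nfkbia averages 4282 in SL and 1780.0 in LL.

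Whether the first LPS dose altered the response to the second was tested as the interaction, the change from LS to LL minus the change from SS to SL. In microglia 40 of 10024 genes were called, 9 positive and 31 negative. More were called by DESeq2, with a block for the replicate number and without the filter on low counts, and by DESeq2 the signs were closer to even. Cd52 had an interaction of -2.60 ± 0.27 on the log2 scale (adjusted p = 0.00034), with 289 ± 10.5, 2661 ± 501, 918 ± 140.1 and 1397 ± 119.8 CPM in SS, SL, LS and LL. Fth1 had -1.77 ± 0.20 (adjusted p = 0.00043) and C3, the central complement component gene, -3.74 ± 0.73 (adjusted p = 0.032), with a microglial mean of 0.02 of that in the class with the highest mean. Positive interactions, that is smaller falls, were found for Slc2a5 (4.58 ± 0.58, adjusted p = 0.0014), Fcrls (1.90 ± 0.32, adjusted p = 0.015), the thromboxane synthase gene Tbxas1 (2.13 ± 0.34, adjusted p = 0.0073) and Nav2 (2.15 ± 0.42, adjusted p = 0.036). Tnfsf13b, which encodes a B-cell survival factor, was at 0 CPM in SS, 50.8 ± 6.34 in SL, 16.2 ± 3.05 in LS and 32.6 ± 7.15 in LL (adjusted p = 0.0015). The formyl peptide receptor gene Fpr2 was at 0, 65.2 ± 7.7, 9.16 ± 6.86 and 12.2 ± 0.286 CPM in the same order (adjusted p = 0.0056), and Aoah, whose product inactivates LPS, at 0, 89.1 ± 17.4, 10.8 ± 5.33 and 47.1 ± 19.2 CPM (adjusted p = 0.021). Of 18 homeostatic genes, 2 had a positive interaction, and 14 when adjusted over the list alone; the camera call was lost with an estimated correlation (adjusted p = 0.828). The count was 19 without SS_1, 12 without SS_2, 123 without SL_2, 25 without LS_2 or LL_1, and 24 without LL_2.

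In endothelial cells, astrocytes and oligodendrocytes edgeR called 0 genes for the interaction. At an unadjusted p under 0.05 there were 1002, 1255 and 220 genes, and DESeq2 called 71, 230 and 2. With a block for the replicate number, edgeR called genes in endothelial cells and oligodendrocytes. Adjusted over the list alone, 7 of 21 endothelial NF-kB targets and 7 of 16 acute-phase genes had a negative interaction, against none of 29 interferon-stimulated genes. With an estimated correlation the adjusted p was 0.401 for NF-kB targets, 0.434 for the acute phase and 0.765 for interferon-stimulated genes. In astrocytes, 10 of 11 A1, 12 of 13 pan-reactive and 14 of 30 interferon-stimulated genes had a negative interaction when adjusted over the list alone, and the adjusted p with an estimated correlation was 0.148, 0.159 and 0.195. Without SL_2 the edgeR count was 297 in astrocytes and 5 in endothelial cells, and without SL_1 it was 1 and 4.

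The first LPS dose, averaged over both second injections, was called in 38 microglial genes, 22 higher and 16 lower. Tmem176a, a membrane protein gene of myeloid cells, rose by 1.16 ± 0.16 (adjusted p = 0.0082), the lysosomal protease gene Ctsh by 0.88 ± 0.16 and Lhfpl2 by 1.03 ± 0.16. Samsn1 fell by 0.85 ± 0.13, Klf7 by 0.78 ± 0.13, Rhoc by 1.34 ± 0.24 and the chemokine gene Ccl5 by 3.63 ± 0.44. The count was 6 without SS_1, 10 without SS_2, 113 without SL_2, 4 without LS_2, 7 without LL_1 and 9 without LL_2, and 25 with doublets kept. In the other 3 classes edgeR called 0 genes, with 1078 endothelial, 1347 astrocytic and 265 oligodendrocytic genes at an unadjusted p under 0.05, and DESeq2 called 129, 213 and 1. A block for the replicate number gave edgeR calls in each of these 3 classes. Leaving out SL_2 gave 239 in astrocytes and 28 in endothelial cells, without SS_2 there were 8 endothelial calls, and without LS_2 there was 1 in astrocytes.

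The second LPS dose, averaged over both first injections, was called in 2513 microglial, 1472 endothelial, 588 astrocytic and 35 oligodendrocytic genes. Endothelial counts were 740 without LL_1 and 951 without LL_2. Astrocytic counts were 255 without SS_1, 105 without SS_2, 1481 without SL_2, 215 without SL_3, 284 without LS_1, 149 without LS_2, 87 without LL_1 and 152 without LL_2. For oligodendrocytes they were 17 without SS_2, 22 without SL_3, 18 without LS_1 or LL_2, 20 without LS_2 and 19 without LL_1.

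The size of the whole second-hit response was compared through a score per library, the mean log2 CPM of genes called higher minus that of genes called lower for LPS on day 14, with the first injection left out of the choice of genes. In microglia, over 1140 higher and 989 lower genes, the score rose by 2.75 from SS to SL and by 1.69 from LS to LL, 61.5% as much. The difference was -1.06, with an exact permutation p of 0.0167 (2-sided, adjusted p = 0.0333 over the 4 classes), the smallest p that the 60 arrangements allow. With fewer libraries the smallest p is larger. The exact p was 0.0556 with SL_1, SL_2 or SL_3 left out in turn. Every group then holds 2 libraries and each of the 36 arrangements has a mirror image, so no smaller 2-sided p is possible. It was 0.0417 without LL_1 or LL_2 and 0.0333 without SS_1 or LS_1. Without SS_2 or LS_2 the exact p was 0.0667, although the 30 arrangements were as many as without SS_1 or LS_1, so fewer arrangements alone do not account for it. Endothelial cells had rises of 2.99 and 2.03 over 1188 genes (67.7%, difference -0.97, exact p = 0.0833, adjusted p = 0.111), and without SS_1 the exact p was 0.0333; the difference was -0.64 without SS_2 and -0.60 without LS_2. Astrocytes had 3.10 and 2.10 over 178 genes (67.9%, difference -0.99, exact p = 0.117). The astrocytic difference rested on single libraries: it was 0.068 (104.3%) without SS_2, where the score held 1 gene, -0.20 without LS_2, -0.49 without SL_1, -0.60 without SL_2, -0.35 without SL_3 and -0.62 without LS_1. In oligodendrocytes the rises were 5.17 and 3.47 (67.1%, difference -1.70, exact p = 0.0167, adjusted p = 0.0333), but the score held only 3 genes, and over the 100 genes with the smallest p the exact p was 0.15. Without SS_2, SL_1, SL_2, SL_3, LL_1 or LL_2 the exact p with the called genes was 0.3, 0.0556, 0.333, 0.333, 0.125 and 0.125, and the difference was -0.65 without SS_2, -0.93 without SL_2 and -0.76 without SL_3. In endothelial cells the 100 genes with the smallest p gave an exact p of 0.0333.

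**Figure D3:**
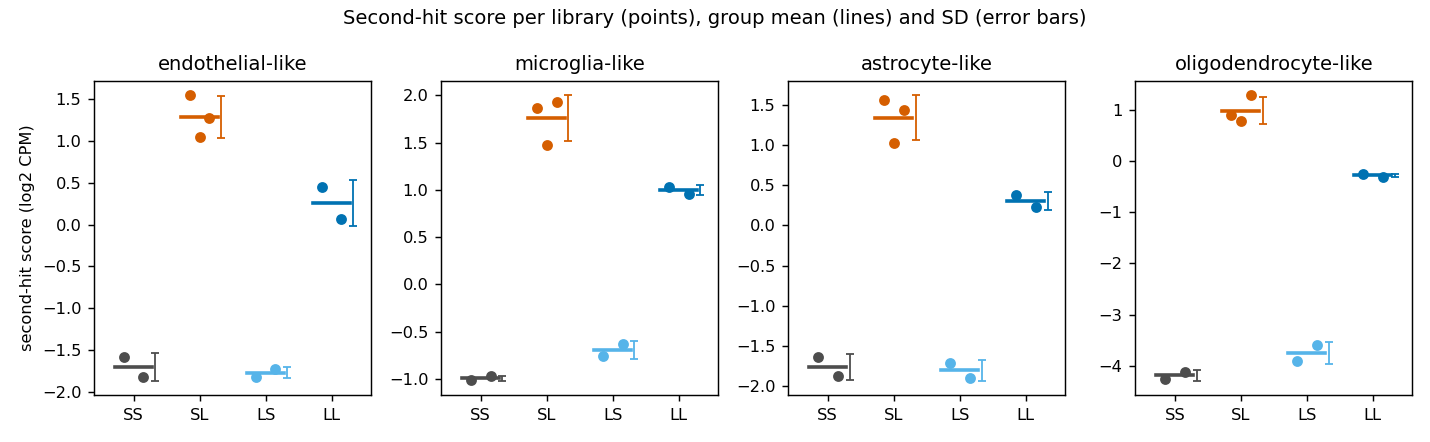
Second-hit score (log2 units, vertical axis) per library in the groups SS, SL, LS and LL for 4 cell classes, with points for libraries, lines for group means and error bars for the SD; the vertical scale differs between classes. Microglial means are -0.99 in SS, 1.76 in SL and -0.69 in LS, and the LL mean lies between those of LS and SL.

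Shares of cells were compared between the 5 libraries with LPS on day 14 and the 4 without, and likewise for the first injection. No class passed after adjustment over 17 classes, the smallest adjusted p being 0.081 for the second injection and 0.607 for the first. With 126 splits, 1 class at the smallest possible exact p could not pass this adjustment alone, so the lack of a call says little. Before adjustment, oligodendrocyte precursors were 7.91 ± 1.65% of cells after LPS and 12.5 ± 0.71% after saline (exact permutation p = 0.0079, the smallest that 126 splits can give). Microglia were 7.30 ± 1.72% against 3.49 ± 1.51% (exact p = 0.0238) and endothelial cells 10.4 ± 1.08% against 8.63 ± 0.99% (exact p = 0.0159). Mural cells were 1.77 ± 0.333% against 2.57 ± 0.275% and neural progenitors 3.399 ± 0.28% against 4.201 ± 0.285% (exact p = 0.0238 each), and inhibitory neurons 1.41 ± 0.752% against 0.431 ± 0.311% (exact p = 0.0476). By library, inhibitory neurons were 0.645 and 0.345% in SS, 0.656, 0.748 and 2.492% in SL, 0.706 and 0.028% in LS, and 1.692 and 1.46% in LL. In LS_2 they were 2 cells. Some shares followed the replicate number, which the test ignores: granule neurons were 6.411% in SS_1 and 7.143% in LS_1, against 0.862% in SS_2 and 0.855% in LS_2. All are shares of dissociated cells among barcodes whose lowest UMI total differed between libraries, from 2508 to 4509. The neural progenitor cluster held 0 of its fixed markers among its 10 leading genes, which included the cell-cycle genes Hmgb2, Ube2c and Top2a. Whether it held dividing cells of other types was not tested. Cells in clusters without a name, whose naming limits were set after the clusters were seen, made up 2.24% in SS, 3.45% in SL, 1.59% in LS and 3.66% in LL.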

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

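Of the tests in this part, those of single libraries in microglia, of a common scaling and of well-expressed members in endothelial cells, and of free RNA for Saa3 and Lcn2 were chosen only after the result was seen. The oligodendrocyte fit with a factor for the libraries with the highest median UMI count was also added after the data were seen.

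The second-hit score of microglia differed between mice with and without LPS on day 3 by -1.06, the rise from LS to LL being 61.5% of that from SS to SL (exact permutation p = 0.0167). Unequal class totals would bring this to at least 90% once the totals are equal, but with every library thinned to 422582 microglial UMIs it was 61.3%, over 1340 genes; cells per library (120 to 609) and UMIs per cell were not made equal. RNA from cells of the other named classes was argued against by the 278 score genes with their highest class mean in microglia, over which it was 53.5% (exact p = 0.0167). Clusters without a name, including that led by S100a8 and S100a9 with its largest share in SL, had no class mean. RNA from their cells was therefore not tested. A single library was argued against by the highest percentage with any 1 of the 9 left out, 69.6%, although the exact p was then above 0.05 in 5 of the 9 settings. The settings without an SL library could not have given an exact p under 0.05, but those without SS_2 or LS_2 could. Part of the difference lay in the groups given saline on day 14, with a mean score of -0.69 in LS and -0.99 in SS. The rest lay in the groups given LPS on day 14, with 1.76 in SL and 0.997 in LL. A candidate explanation is that LPS on day 3 leaves microglia less responsive to LPS on day 14, a hypothesis found and tested on the same data, and a different mix of microglial states or of captured cells, or of cell numbers and UMIs per cell, stays open and was not tested.

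In endothelial cells the mean log2 change of 29 interferon-stimulated genes was 2.22 from SS to SL and 2.44 from LS to LL, 110% as much, while that of 21 inflammatory cytokines and NF-kB targets was 2.82 and 1.20, 42.6% as much, and that of 16 acute-phase genes 4.07 and 1.94, 47.7%. A common scaling of every response would put the first 2 lists within 15 points of each other, and they stood 67.4 points apart, but the difference of the changes, 1.84, had an exact permutation p of 0.15, so this explanation cannot be told apart from responses that differ by list. RNA from other cells stays open too. Over members highest in endothelial cells (12 interferon-stimulated, 1 inflammatory) the gap was 55.1 points (exact permutation p = 0.117). That lay beyond the limit of 30 set before the result was seen, but 1 inflammatory gene is too few to decide. Over members at 0.5 or more of the top class (18 and 7) the gap was 57.7 points, left undecided by its exact p of 0.133. The requirement of an exact p under 0.05 was added after these values were seen. The gap between the lists within SL libraries ranged from 0.27 to 1.27 log2 CPM, a wide spread that keeps the question open.

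Transcripts of acute-phase genes appeared in classes that may not make them. Saa3 in SL oligodendrocytes was at 460.5, 220.2 and 213.1 CPM in SL_1, SL_2 and SL_3 (here of plain class totals, without the TMM factors used elsewhere), at most 1.48 times the mean of immature, granule and Cajal-Retzius neurons of the same library. That lay in the range set for free RNA, but the range takes cells of equal depth. Library medians were 13467 to 19844 UMIs per cell in oligodendrocytes and at most 10307.5 in these neurons, so the ratio does not decide. For Lcn2 in astrocytes, free RNA was argued against: at 8250.0, 1457 and 4262 CPM on the same plain scale it was at least 16.8 times the neuron mean in each of the 3 libraries. Why SL_2 had a lower level than the other 2 was not tested.

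Several other results stood out by a difference between groups or in cells outside the comparisons. In oligodendrocytes the second-hit score differed by -1.70 between mice with and without LPS on day 3, over 3 genes. The interaction of both injections was called by edgeR in 40 genes in microglia, where it was 19 without SS_1, 12 without SS_2, 123 without SL_2, 25 without LS_2 or LL_1 and 24 without LL_2. In border macrophages it was called in 83 genes, and in 53 without SS_2, 191 without SL_2, 47 without SL_3, 44 without LS_2 and 40 without LL_2. In fibroblasts it was called in 15 genes, and in 26 without SS_1, 2 without SS_2, 23 without SL_2, 4 without SL_3, 2 without LL_1 and 6 without LL_2. An unnamed cluster of 271 cells led by S100a8 and S100a9, with markers of both monocytes and neutrophils, held 1.34 ± 0.35% of cells in SL, against 0.038 ± 0.018% in SS, 0.194 ± 0.012% in LS and 0.542 ± 0.129% in LL, a difference that was not tested.

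The 5 libraries with LPS on day 14 were set against the 4 without in a model of that injection alone, and 100 of the splits into 5 and 4 libraries were drawn, the real one included. In endothelial cells 1 split, the real one, gave as many calls as its 1188, and the highest other gave 95; in astrocytes 1 split gave as many as 178, and the highest other gave 39. No other drawn split gave as many in either class. In microglia 1 split gave as many as 2129 and the highest other gave 1135. That other split set the 3 SL libraries and LL_2 apart from the rest. These splits do not exclude chance outright, because not all splits were drawn. They also take the libraries as exchangeable, although same-numbered SS and LS libraries were closer than libraries of 1 group. For oligodendrocytes 4 of the 100 splits gave 3 or more calls and the highest other gave 321, many times the real count. That split set apart SS_2, SL_3, LS_2 and LL_2, the library with the highest median UMI count per barcode in each group, which points to a structure of the samples. Of these, 3 also share replicate number 2, and the next-highest split, with 15 calls, set apart the 4 libraries numbered 1, so depth and whatever the numbers share were not separated. With a factor for those libraries, 99 genes were called for SL against SS, 4 for LL against LS and 18 for LL against SL, and with a replicate block 221, 4 and 104. For the first injection alone the real count was 0 in each of the 4 classes; 100 of 100 splits give as many whatever the data, so the splits say nothing about chance. The highest others were 1188 in endothelial cells, 2129 in microglia and 178 in astrocytes, each from the split by the second injection, and 321 in oligodendrocytes from the split by median UMI count.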

How the results depend on the processing

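The factor for the library with the highest median UMI count per barcode in each group was added after the data were seen. With 2 or 3 libraries per group, counts of called genes moved more than directions, and the causes were not tested. Counts below are genes called. DESeq2's size factors and the stricter cell filter moved no count in the 4 main classes by over 1.5 times, and no share of cells changed its side of the threshold in any setting. For the shares this says little, because the adjusted exact test could hardly pass with so few libraries. Without the filter on low counts, where more genes near 0 are tested, LL against LS called 8 genes in astrocytes, 305 in endothelial cells, 728 in microglia and 38 in oligodendrocytes; LL against SL called 659 in endothelial cells, 946 in microglia and 221 in oligodendrocytes; LS against SS called 62 in microglia and 1 in oligodendrocytes; SL against SS called 396 in oligodendrocytes; the interaction was called in 14 astrocytic, 59 endothelial, 259 microglial and 58 oligodendrocytic genes, the first injection averaged in 1, 91, 283 and 91, and the second averaged in 340 in oligodendrocytes. DESeq2's Wald test called 40, 303 and 5 genes for LL against LS and 1016, 601 and 46 for LL against SL in astrocytes, endothelial cells and oligodendrocytes, 22 for LS against SS in microglia and 117 for SL against SS in oligodendrocytes. For the interaction it called 230 in astrocytes, 71 in endothelial cells, 111 in microglia (50 positive, 61 negative) and 2 in oligodendrocytes, for the first injection averaged 213, 129, 90 and 1, and for the second averaged 1058 in astrocytes and 94 in oligodendrocytes. Leaving out genes under 10% of their level in the class with the highest mean gave 1 astrocytic and 0 oligodendrocytic genes for LL against LS, 247 and 1 for LL against SL, 10 microglial genes for LS against SS, and 21 and 12 oligodendrocytic genes for SL against SS and the second injection averaged. In a fit of only the compared groups, which leaves fewer degrees of freedom, astrocytes gave 376 for SL against SS, 17 for LL against LS and 135 for LL against SL, microglia 499 for LL against LS and 3 for LS against SS, and oligodendrocytes 0 for LL against LS. With doublets kept, microglia gave 196 for LL against LS and 25 for the first injection averaged. Classes assigned by marker score gave 1 for LL against LS in oligodendrocytes. In a model of the second injection alone, 178 astrocytic and 3 oligodendrocytic genes were called for it. The factor for the libraries with the highest median UMI count gave 99, 4 and 18 oligodendrocytic genes for SL against SS, LL against LS and LL against SL, and 90 for the second injection averaged. Over the 100 genes with the smallest p, the second-hit score difference was -1.19 in oligodendrocytes (exact p = 0.15) and -0.78 in endothelial cells (exact p = 0.0333).

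The labels give libraries of different groups the same replicate numbers without saying what they share. Deviations of same-numbered libraries from their group means correlated from -0.128 to 0.632 in astrocytes, -0.097 to 0.554 in endothelial cells, -0.265 to 0.274 in microglia and -0.054 to 0.554 in oligodendrocytes, over 0.1 in 5, 4, 3 and 10 of 12 pairs. In a group of 2 libraries the deviations mirror each other, so some of the 12 pairs repeat a value. The numbers were not taken to pair the libraries because in no class were all pairs over 0.1, a rule that does not exclude a shared factor. Same-numbered SS and LS libraries did deviate together, with correlations of 0.632, 0.554, 0.274 and 0.554, and their counts were closer (chi-square per degree of freedom 13.74 for number 1 and 43.55 for number 2) than those of libraries of 1 group (84.61 to 132.15), so something that the labels do not name may be shared. With a replicate block, the counts were 737 for SL against SS, 0 for LL against LS and 2 for the first injection averaged in astrocytes; 484 for LL against SL, 27 for the interaction and 41 for the first injection averaged in endothelial cells; 532 for LL against LS, 12 for LS against SS, 119 for the interaction and 112 for the first injection averaged in microglia; and 221 for SL against SS, 4 for LL against LS, 104 for LL against SL, 2 for the interaction, 169 for the second averaged and 9 for the first averaged in oligodendrocytes. Cell-cycle genes of microglia in SL against SS, with a median log2 change of -0.29, were not called by camera, whose direction was up, and were called lower with the block (adjusted p = 5.8e-05).

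With 1 library left out at a time, counts in endothelial cells ranged from 664 to 1757 for SL against SS, 62 to 223 for LL against LS, 0 to 534 for LL against SL, 0 to 5 for the interaction, 740 to 1484 for the second injection averaged and 0 to 28 for the first. Those in microglia ranged from 1129 to 2378 for SL against SS, 58 to 433 for LL against LS, 0 to 16 for LS against SS, 64 to 658 for LL against SL, 12 to 123 for the interaction and 4 to 113 for the first injection averaged. Astrocyte counts ranged from 23 to 2398 for SL against SS, 0 to 4 for LL against LS, 0 to 1663 for LL against SL, 0 to 297 for the interaction, 87 to 1481 for the second injection averaged and 0 to 239 for the first. Oligodendrocyte counts ranged from 14 to 86 for SL against SS, 0 to 3 for LL against LS, 0 to 15 for LL against SL and 17 to 51 for the second injection averaged. The second-hit score difference ranged from -1.18 to -0.88 in microglia, -1.24 to -0.60 in endothelial cells, -1.45 to 0.068 in astrocytes, where the sign turned without SS_2, and -1.64 to -0.65 in oligodendrocytes. Of 1274 list results, 449 that were called with the preset correlation lost the call with an estimated one. The libraries are named beside the counts that they moved.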

Other observations

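No test in this part was chosen after its result was seen, but which classes and lists to describe was. Cells at the borders of the brain also changed with LPS on day 14. In border macrophages, whose cluster was led by Pf4, Ifi27l2a and Mrc1 with the acute-phase gene Saa3 and the chemokine gene Ccl7 among its top 10, edgeR called 1014 genes for SL against SS, 532 higher and 482 lower. Saa3 was at 27.5 ± 38.8 CPM in SS, 100629 ± 17829.5 in SL, 8.58 ± 3.04 in LS and 12941 ± 701 in LL (adjusted p = 0.00022 for LPS on day 14 averaged over the first injection). Over that same contrast Tslp, the gene of a cytokine that acts on dendritic cells, fell by 3.99 ± 0.39 (adjusted p = 3.7e-06), and the eosinophil attractant gene Ccl24 by 4.84 ± 0.74 (adjusted p = 0.013). In SL, homeostatic microglia genes measured in these cells fell in 10 of 16 members, and 11 fell and 1 rose when adjusted over the list alone (adjusted p = 0.248 with an estimated correlation). Glycolysis genes rose in 9 of 14 members, and in 11 adjusted over the list alone (adjusted p = 0.247 with an estimated correlation). The count for SL against SS was 658 without SS_1 and 463 without SS_2. For LS against SS, border macrophages had 16 genes higher and 14 lower, 30 in all, 11 without SS_1 and 10 without LS_2, and for the first injection averaged 110 higher and 55 lower, 165 in all, 64 without SS_1, 45 without LS_2, 77 without LL_1 and 78 without LL_2. Ependymal cells, with C3 and the LPS-binding protein gene Lbp among their leading genes, were tested in 8 libraries. For SL against SS, 520 genes rose and 405 fell, with 25 of 26 interferon-stimulated and 14 of 14 MHC class I genes higher, also when adjusted over the list alone, and both lists kept their camera call with an estimated correlation (adjusted p = 0.0279 and 0.0256). The markers of ependymal cells themselves fell in 5 of 7 members in SL, 6 when adjusted over the list alone (adjusted p = 0.306 with an estimated correlation), and rose in 3 of 7 in LL against SL, 6 when adjusted over the list alone (0.378). Markers of erythroid cells fell in 2 of 4 members in SL, of mural cells in 2 of 5, of oligodendrocytes in 2 of 9 and of immature neurons in 2 of 7, and in 4, 2, 2 and 4 when adjusted over the list alone (adjusted p with an estimated correlation 0.356, 0.356, 0.555 and 0.539), and whether the mix of captured cells changed was not tested. For LL against SL, 14 of 14 class I genes and 12 of 16 NF-kB targets were lower in ependymal cells, and 14 and 16 when adjusted over the list alone (adjusted p = 0.0302 and 0.0762 with an estimated correlation). The ependymal count for SL against SS, 925, was 575 without SS_1, 234 without SS_2 and 1402 without SL_2, and that for LL against SL, 706, was 432 without SL_1, 1219 without SL_2, 296 without LL_1 and 241 without LL_2. Fibroblasts had 181 genes higher and 45 lower in SL than in SS, a total of 226 that was 147 without SS_1, 120 without SS_2 and 140 without SL_1. Saa3 in fibroblasts was at 0, 26513 ± 7006, 2.3 ± 0.224 and 426 ± 168 CPM in SS, SL, LS and LL (adjusted p = 6.4e-06 for LPS on day 14). In choroid plexus cells, for which 7 libraries had enough cells, LL against SL called 49 genes higher and 238 lower, with 19 of 29 interferon-stimulated and 12 of 15 class I genes lower and 25 and 14 when adjusted over the list alone (adjusted p = 0.203 for both with an estimated correlation). That choroid plexus count, 287, was 104 without SL_1, 541 without LL_1 and 69 without LL_2.

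The oligodendrocyte precursor cluster mixed 2 stages, with 3 progenitor and 3 committed-precursor markers among its 10 leading genes, and some of its cell-cycle genes were lower after LPS on day 14 with either first injection. Whether the mix of stages shifted was not tested. In SL against SS 17 of 27 cell-cycle genes fell, 26 when adjusted over the list alone, and the list kept its call with an estimated correlation (adjusted p = 0.0285). In LL against LS 8 of 27 fell, 20 when adjusted over the list alone, with an adjusted p of 0.0895 with an estimated correlation. Birc5, whose product takes part in chromosome segregation, was at 80.2 ± 3.4 CPM in SS, 11.5 ± 11.5 in SL, 78.2 ± 24 in LS and 9.78 ± 0.982 in LL, and fell by 2.79 ± 0.37 for LPS on day 14 averaged over the first injection (adjusted p = 0.0027). The inhibitor gene of cyclin-dependent kinases Cdkn2c fell by 1.45 ± 0.22, while Rtp4 rose by 3.45 ± 0.27 (adjusted p = 2e-05). Interferon-stimulated genes rose in 16 of 24 members in SL against SS and 9 of 24 in LL against LS, 22 and 17 when adjusted over the list alone (adjusted p = 0.0206 and 0.0895 with an estimated correlation). The averaged contrast called 103 genes higher and 219 lower, 322 in all, and 174 without LL_1. The count for SL against SS, 178, was 87 without SS_1, 45 without SS_2, 82 without SL_1 and 84 without SL_3, and that for LL against LS, 62, was 102 without SL_2, 22 without LS_1 and 1 without LL_1. In excitatory neurons 4 of 20 cholesterol synthesis genes fell in SL against SS, 10 when adjusted over the list alone, and the list kept its call with an estimated correlation (adjusted p = 0.0145).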
